A study of Mus musculus with 12 samples.

How the data were processed

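Blood was taken from 12 mice, 6 with a Tff3 knockout and 6 wild type, and each genotype held 3 males and 3 females. Per the labels' protocols, peripheral blood went into RNA-stabilising tubes, the pellet after centrifugation was extracted for total RNA including miRNA, and biotin was attached in a microfluidic primer extension assay. The labels speak of blood from each animal, so the arrays were treated as separate mice. Tff3 messenger RNA was not among the measurements, so the genotype labels could not be checked against their target. The design text calls the knockout a knock-down. The scanner, the background method and the way spots were combined are not given in the sources used here.

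The authors deposited 2 tables of intensity, each with 710 miRNAs on 12 arrays. In the raw table the deposited intensity is linear and some values lie below 0, so a background had been subtracted. The highest raw values came close to one another on 3 arrays (62415, 64243 and 64623), and a scanner ceiling cannot be ruled out there. In the normalized table the authors' intensity is linear, all 12 arrays share nearly 1 distribution with a top value of 45723 and array medians from 99.7 to 104, and the lowest values are set to 1. Each normalized array kept the probe order of 1 raw column (Spearman rho of at least 0.99997). The shared distribution was not the mean of the raw columns, whose highest mean quantile was 50821, so the normalization is quantile-like with an unknown target. Neither table flags which miRNAs were above background.

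The design fixed before the data were examined was to start from the raw table. The names of its wild type columns match no single mouse and give no sex, and every planned model needs sex. For these columns the next best normalized array had a rho of only 0.892 to 0.909, so their probe order could identify the mice. That match was not used to assign sex. The main values are therefore log2 of the authors' normalized intensity with a floor of 1. The raw table served for array brightness and for alternatives of the genotype comparison without a sex term. All 12 columns of both tables were used.

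Each miRNA was tested on the log2 scale with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, Benjamini-Hochberg adjustment over 710 miRNAs, threshold 0.05). Knockout against wild type carried sex as an additive term, and female against male carried genotype. The comparisons within males, within females and of the genotype effect between sexes came from 1 model of the 4 groups of 3 mice. Values near the floor have a large spread on the log2 scale, and folds against the floor depend on it. The number of arrays limits the precision: the median standard error of a genotype difference was 0.26 on the log2 scale, and 0.37 within 1 sex. Array measures were compared with exact permutation tests, two-sided.

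There were 15 lists of miRNAs fixed before the data were examined: erythroid, myeloid, lymphoid and platelet markers; liver and gut epithelium, muscle and brain markers; the let-7 family; the miR-17-92 cluster and its paralogs; inflammation; glucose and lipid metabolism; the p53-linked miR-34 family; the imprinted Dlk1-Dio3 cluster; the miR-297, miR-466, miR-467 and miR-669 family of the Sfmbt2 gene; and the X chromosome. The list called the miR-34 family also holds miR-192, miR-194 and miR-215, so it is wider than that family. Lists were tested with camera at a preset correlation of 0.01, adjusted over the 15 lists. Alternatives were camera with an estimated correlation, fry and, chosen after seeing the data, an exact permutation test of the list mean per mouse. The limma p of list members were also adjusted over their own list alone, a step outside the design fixed beforehand. It is not corrected for the number of lists, some of which overlap, or of comparisons, so some of its passes may be due to chance. Hairpin positions were looked up by name in a RefSeq gene table of assembly GRCm38.p6, only to tell which lie inside Sfmbt2, inside the Dlk1-Dio3 interval or on the X chromosome. It held 52 of the 54 measured Sfmbt2 family members, 69 of 72 Dlk1-Dio3 members and 70 of 77 X chromosome members.

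The rule for named miRNAs was fixed before the data were examined. It took the 10 smallest p of the genotype comparison if fewer passed, up to 5 passing in each direction (or the 2 smallest p) of each other comparison, the 2 smallest p of each list, 2 X chromosome members for sex, and the 5 brightest miRNAs. A miRNA named outside this rule is said to be chosen after its values were seen.

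The models were tested on simulated data with the arrays' own spread, in 20 simulations with 40 of 710 miRNAs changed. The changed miRNAs were drawn only from those above a cut on mean intensity, and the noise was independent between miRNAs. The shares recovered therefore do not cover dim miRNAs or correlated ones. Each simulation mixed changes of 1 and of 2 log2 units in equal number, and the larger ones ease the adjusted threshold for the smaller. The shares thus do not cover data with few or only small changes. For knockout against wild type, 67.5% of changes of 1 log2 unit and 98.5% of changes of 2 were recovered. Within males the shares were 26.8% and 82.0%, within females 34.8% and 85.0%, for the difference between sexes 7.00% and 55.8%, and for female against male 64.8% and 96.3%. Alternatives covered the floor, an offset of 16, filters on dim miRNAs, the variance model, array weights, the covariate, the replicate number as a block, the source and scaling of the values, and each mouse left out in turn. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.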

Results

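Blood miRNA of Tff3 knockout and wild type mice was measured to ask whether loss of Tff3, a trefoil peptide secreted mainly by mucous epithelia, changes the miRNA profile of blood. Each array held 710 miRNAs, and each of the 4 combinations of genotype and sex had 3 mice. The brightest miRNAs over all 12 arrays were miR-1937a, miR-486, miR-1937b, miR-16 and miR-15b; miR-486 and miR-16 are abundant in red cells. None of these 5 passed the genotype test. Their knockout minus wild type differences were -0.06, -0.04, -0.28, 0.15 and 0.28 on the log2 scale, in that order, and the sign for miR-1937a and miR-486 turned under some alternatives. miR-1937a sat at the highest value the arrays share (15.48) on 9 of 12 arrays, so its difference is bounded by that ceiling. The median raw intensity per array was 106 ± 42.6 in knockout and 101 ± 21.1 in wild type mice (SD, n = 6 each; exact permutation p = 0.840 over 924 splits). The share of miRNAs at or below 0 was 4.18% ± 2.46 and 4.37% ± 1.60 (SD, n = 6 each; exact permutation p = 0.898). In the normalized values 107 miRNAs sat at the floor on at least 1 array.

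In the comparison of all knockout with all wild type mice, 1 list passed camera at the preset correlation. It was the miR-297, miR-466, miR-467 and miR-669 family, a rodent family whose largest cluster lies in an intron of the imprinted gene Sfmbt2. Of its 54 measured members 48 were higher in knockout blood, with a median difference of 0.35 on the log2 scale. The list passed camera (adjusted p = 1.93e-10), with adjusted p = 0.408 with an estimated correlation, so the call rests on the preset one. The family mean per mouse was 7.99 ± 0.12 in knockout and 7.57 ± 0.36 in wild type mice (log2 intensity, SD, n = 6 each; exact permutation p = 0.0325, adjusted over 15 lists 0.487). Unadjusted limma p under 0.05 was reached by 16 members, all higher in knockout, and 0 passed when adjusted over the list alone (smallest 0.105) or over all miRNAs. miR-467f, 1 of the brightest members, stood at 12.70 ± 0.57 in knockout and 11.04 ± 1.15 in wild type mice (log2, SD, n = 6 each), and miR-467b* at 10.78 ± 0.57 and 9.32 ± 0.94. Wild type replicates 1 and 2, both male, had 12.55 and 12.36 for miR-467f, inside the knockout range of 11.71 to 13.19. The 42 members with all hairpins inside Sfmbt2 had a median difference of 0.35, and the 7 with none there had 0.37.

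The miR-181 family, known for its role in lymphocyte development, was lower in knockout blood in all 4 measured members. miR-181a was at 7.43 ± 0.51 in knockout and 8.66 ± 0.68 in wild type mice (log2, SD, n = 6 each), a 2.33-fold difference (limma adjusted p = 0.333). miR-181c was at 6.59 ± 0.46 and 7.37 ± 0.20. For miR-181b and miR-181d, named after their values were seen, the differences were -1.34 and -0.34. Among 15 lymphoid markers 4 passed when adjusted over the list alone (smallest 0.0223) and 0 over all miRNAs. Of these, miR-181a, miR-181c and miR-181b were lower in knockout, while miR-30b, a broadly expressed miRNA, was higher, at 13.37 ± 0.19 against 12.78 ± 0.39. The lymphocyte-enriched miR-342-3p was lower (-0.63 ± 0.23, log2 difference ± SE, limma adjusted p = 0.413), while miR-150 and miR-155 were at 0.14 and 0.67. All of these were named after their values were seen. Of the 15 lymphoid markers 10 were higher in knockout. The lymphoid list as a whole did not pass camera (median 0.07, mean -0.13, adjusted p = 0.674), and the signs of its median and mean differed. Changes in either direction passed fry's mixed test in 2 of the 15 lists, the lymphoid list (adjusted p = 0.00501) and the Sfmbt2 family (0.0351).

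**Figure D1:**
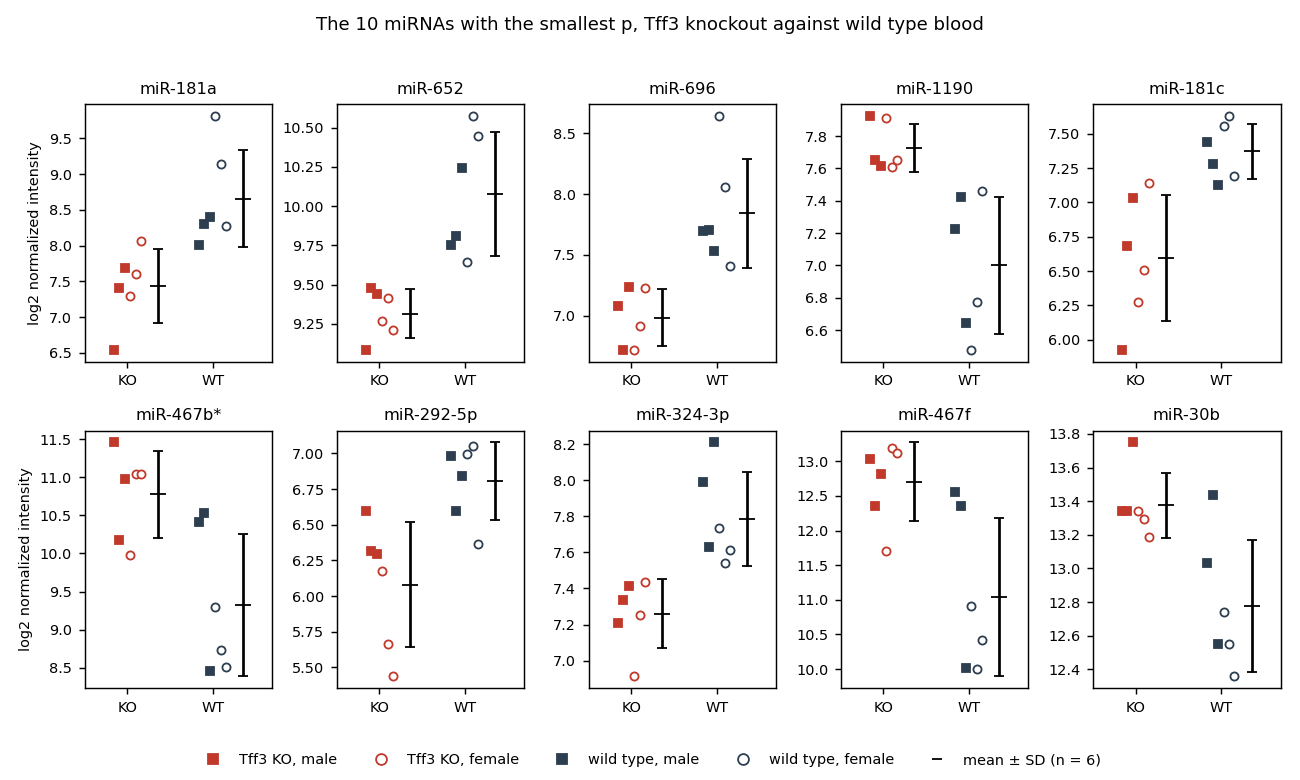
Log2 normalized intensity (vertical axes, not starting at 0) of the 10 miRNAs with the smallest p between Tff3 knockout (red) and wild type (dark) mice, 1 point per mouse, squares for males, open circles for females, bars for mean ± SD of 6 mice. miR-181a had means of 7.43 and 8.66 and miR-467f of 12.70 and 11.04; none passed adjustment over all miRNAs (adjusted p = 0.333).

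No single miRNA passed adjustment over all 710 by limma, where the smallest adjusted p was 0.333, and a test of each miRNA on its own spread alone also called 0. At an unadjusted limma p under 0.05 there were 67 (33 higher, 34 lower), against 35.5 expected by chance. Other splits of the mice with the sexes balanced gave a median of 26 and up to 82, so chance was not excluded. Other miRNAs among the 10 smallest p were miR-652 (-0.76 ± 0.19, log2 difference ± SE), miR-696 (-0.86 ± 0.22), miR-292-5p (-0.73 ± 0.20), miR-324-3p (-0.53 ± 0.15) and miR-1190 (0.73 ± 0.20). miR-652 lies on the X chromosome, and for it the 6 knockout values (9.08 to 9.48) were all below the 6 wild type values (9.64 to 10.57). The knockout values were also all below the wild type values for miR-696 and miR-324-3p, and all above them for miR-1190. Picking the smallest p favours such separation. When only the brightest 25% of miRNAs (178) were tested, 5 passed: miR-181a, miR-652, miR-467b*, miR-467f and miR-466f-3p (largest adjusted p = 0.0495).

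The remaining 13 lists did not pass camera between genotypes. The let-7 family had 7 of 9 members higher in knockout (median 0.20, adjusted p = 0.273), led by let-7f (0.93) and let-7g (0.62). Erythroid markers had a median of -0.08 (adjusted p = 0.674), with miR-144, a red cell miRNA, at 1.05 and miR-210, which responds to low oxygen, at -0.39. Myeloid (0.01), platelet (-0.12) and miR-17-92 (-0.03) medians were near 0; their leading members were miR-338-3p (-0.46) and miR-27a (-0.37), miR-423-5p (-0.34) and miR-191 (-0.29), and miR-19b (0.44) and miR-19a (0.43). The adjusted p was 0.674 for the first pair of these lists and 0.921 for the miR-17-92 list. Markers of tissue outside blood also failed the test, at adjusted p = 0.674 each: liver and gut epithelium (median -0.16, 8 of 13 lower), muscle (0.35) and brain (0.06). In them miR-122, the main miRNA of hepatocytes, was at 7.42 ± 2.51 in knockout and 9.62 ± 2.63 in wild type mice (log2, SD, n = 6 each). miR-194 differed by -0.44, the muscle miRNAs miR-208b and miR-206 by -1.02 and 1.19, and the neuronal pair miR-212 and miR-132 by -0.32 and -0.26. The difference of miR-206 ran from 0.69 to 1.59 with a mouse left out and was as low as 0.43 under other processing. Inflammation (0.16, with miR-146b at 0.43), glucose and lipid metabolism (0.01, with miR-335-5p at 0.44 and miR-107 at -0.79), the miR-34 family (-0.16, with miR-34c at 0.72), the Dlk1-Dio3 cluster (0.04, with miR-323-3p at 0.79 and miR-539 at -2.13, or -0.73 with a floor of 16) and the X chromosome list (0.01, with miR-362-3p at 0.63) had adjusted p = 0.674 each.

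**Figure D2:**
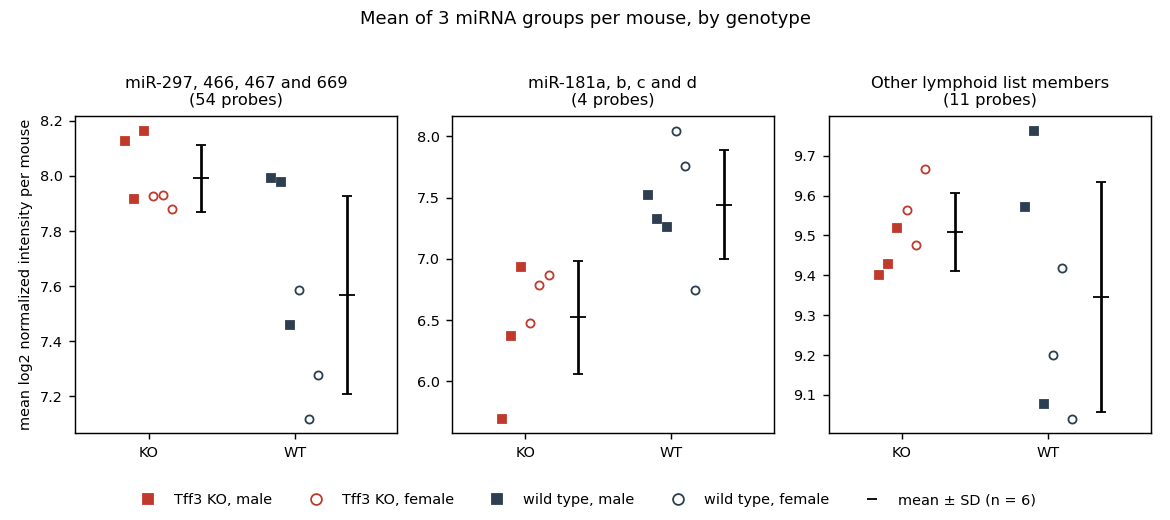
Mean log2 normalized intensity per mouse (vertical axes, not starting at 0) of the miR-297, miR-466, miR-467 and miR-669 family, of the 4 miR-181 miRNAs and of the 11 other lymphoid markers, by genotype, 1 point per mouse, squares for males, open circles for females, bars for mean ± SD of 6 mice. Family means were 7.99 in knockout and 7.57 in wild type, miR-181 means 6.52 and 7.44, and means of the other lymphoid markers 9.51 and 9.35.

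Within males, the 3 knockout and 3 wild type mice differed in 1 miRNA. miR-654-3p, of the imprinted Dlk1-Dio3 cluster, was lower in knockout (limma adjusted p = 0.0175), by an amount that the floor sets. All 3 knockout males were at or near the floor, with intensities of 3.0, 2.8 and 1.0, against 17.2, 18.8 and 46.4 in the wild type males. The fitted difference of -3.60 on the log2 scale shrank to -0.62 with a floor of 16 and -1.19 with an offset of 16. The call was lost there (limma adjusted p = 0.688 and 0.492), without wild type replicate 2 (0.0616) and without wild type replicate 3 (0.0563). It was also lost with trend and robust fitting, with males fitted alone and with the replicate block. At an unadjusted p under 0.05 there were 36 miRNAs, but 15 to 83 under the alternatives and 18 to 62 with a mouse left out. The alternatives include the filters on brightness, which tested fewer miRNAs, so their range mixes counts out of unlike totals. The Sfmbt2 family had a median of 0.21 in males and passed camera (adjusted p = 0.0215; adjusted p = 0.733 with an estimated correlation). Without wild type replicate 3 that median was 0.01 (adjusted p = 0.754), and without knockout replicate 1 or 3 the call was also lost (0.0634 and 0.249), as it was with array weights (median 0.10, adjusted p = 0.511). Without wild type replicate 1, miR-302b and miR-758 passed as well, both named after their values were seen; 2 of 3 knockout males were at the floor for miR-302b and 2 of 3 wild type males for miR-758, so no size is given.

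Within females, 0 miRNAs passed in limma and 62 had an unadjusted p under 0.05 (35 higher, 27 lower). The 2 smallest p belonged to miR-292-5p, of an embryonic stem cell cluster, at -1.05 ± 0.27, and miR-466f-3p, of the Sfmbt2 family, at 1.86 ± 0.51 (log2 difference ± SE, adjusted p = 0.378 each). In the Sfmbt2 family 46 of 54 members were higher in knockout females, 20 with an unadjusted p under 0.05, with a median of 0.47 (camera adjusted p = 7.49e-11; adjusted p = 0.383 with an estimated correlation). Without wild type replicates 5 and 6 together, an alternative chosen after seeing the data, the median was 0.30 and camera no longer called it (adjusted p = 0.947). miR-122 was at 9.16 ± 2.58 in knockout and 11.91 ± 0.66 in wild type females (log2, SD, n = 3 each). Knockout replicate 6 alone, at 12.11, lay among the wild type females. Without it miR-122 passed, at -4.22 (limma adjusted p = 0.0402). The liver and gut epithelium list, which holds miR-122, then passed too (median -0.62, camera adjusted p = 0.0202, against -0.40 and 0.293 with all mice). Without wild type replicate 5, which was at the floor for miR-539, that miRNA passed (0.00966), but all 3 knockout females were at the floor too, so no size is given.

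The genotype effect was then compared between the sexes. By limma 0 miRNAs passed (38 at an unadjusted p under 0.05, and 25 to 70 with a mouse left out). The smallest p were those of miR-654-3p and miR-464 (adjusted p = 0.116 each), both dim. For miR-654-3p the fitted 4.02 rests on the 3 knockout males at or near the floor, and was 1.05 with a floor of 16. The fitted difference of miR-464 was -2.36. miR-464 was at 5.78 ± 0.14 in knockout and 4.38 ± 0.38 in wild type males, and at 4.58 ± 0.24 and 5.55 ± 0.57 in females (log2, SD, n = 3 each). The Sfmbt2 family's difference was larger in females by a median of 0.35 (camera adjusted p = 0.0180; adjusted p = 0.596 with an estimated correlation). Leaving out any 1 of knockout replicates 2 and 4 or wild type replicates 1, 2, 5 and 6 ended that call (adjusted p from 0.117 to 0.278), and so did testing only the brightest 25% of miRNAs (median 0.36, adjusted p = 0.182). Without wild type replicates 5 and 6 together the median was near 0 (adjusted p = 0.811).

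Between females and males, miR-122 had the smallest p, at 10.54 ± 2.26 in females and 6.51 ± 1.11 in males (log2, SD, n = 6 each), a 16.3-fold difference (limma adjusted p = 0.121). On the log2 scale that difference of 4.03 was 3.44 without knockout replicate 6 and 4.51 without knockout replicate 4. The male intensities, 50.6 to 283.5, lie near the array medians of 99.7 to 104, and without detection calls the fold depends on the background in males. miR-122 passed when adjusted over the liver and gut epithelium list alone (0.00252). So did miR-192, another liver and gut miRNA, at 0.96 ± 0.26, named after its values were seen. Over all miRNAs miR-122 passed with an offset of 16 (adjusted p = 0.0486), when only the brighter 50% were tested (0.00164), and without knockout replicate 4 or 6. The liver and gut epithelium list had 12 of 13 members higher in females, with a median of 0.24 (camera adjusted p = 0.0117; adjusted p = 0.359 with an estimated correlation). Without knockout replicate 1 or 6 it no longer passed (0.0527 and 0.0514).

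Platelet markers were higher in females in 9 of 10 members, with a median of 0.39 (camera adjusted p = 0.00944; adjusted p = 0.359 with an estimated correlation; 0.0527 without knockout replicate 1). The list mean was 8.22 ± 0.28 in females and 7.82 ± 0.26 in males (log2, SD, n = 6 each; exact permutation p = 0.0281, adjusted over 15 lists 0.211). miR-191 and miR-423-5p, both bright, were higher in females by 0.47 and 0.46, and neither passed. By limma, 0 of the 10 members passed when adjusted over the list alone (smallest 0.137). miR-126-3p differed by 0.16 and miR-197, the only lower member, by -0.07, both named after their values were seen. Whether the share of platelets differed between the sexes was not tested. The Sfmbt2 family was lower in females in 47 of 54 members, with a median of -0.31 (camera adjusted p = 2.25e-06; adjusted p = 0.359 with an estimated correlation).

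The let-7 family, whose members share 1 seed sequence, split in the comparison of the sexes. let-7i, let-7g, let-7f and let-7a passed when adjusted over the list alone (largest 0.0330), at -0.72, -1.01, -0.91 and -0.56 on the log2 scale, while let-7e differed by -0.40, let-7b, let-7c and let-7d by 0.23, 0.12 and 0.02, and miR-98, at the floor in 1 male, by 1.64; members other than let-7f and let-7g were named after their values were seen. The list median was -0.40 (camera adjusted p = 0.0633; adjusted p = 0.359 with an estimated correlation). At the preset correlation it passed with a floor of 16 (0.0493), in the brighter 50% (0.0130), and without knockout replicate 4 (0.0348) or wild type replicate 2 (0.0282). Erythroid markers, 9 of 11 lower in females, did not pass camera (median -0.13, adjusted p = 0.416) but passed fry's mixed test (adjusted p = 0.00115), and 2 passed within the list alone: miR-451, the main red cell miRNA, at -0.76 and miR-96 at 0.56. In the lymphoid list (median 0.02, adjusted p = 0.956) miR-342-3p passed within it at 0.88. These 3 were also named after their values were seen.

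**Figure D3:**
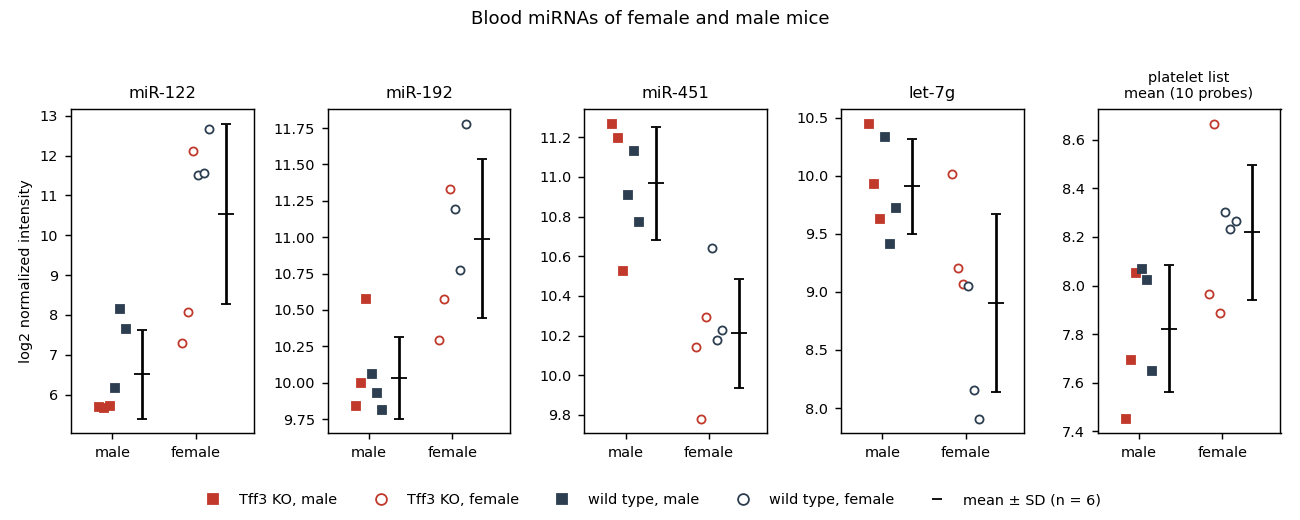
Log2 normalized intensity (vertical axes, not starting at 0) of miR-122, miR-192, miR-451 and let-7g, and the mean of the platelet list, in male and female mice, 1 point per mouse, red for Tff3 knockout, dark for wild type, bars for mean ± SD of 6 mice. miR-122 had means of 6.51 in males and 10.54 in females, and let-7g of 9.91 and 8.90. miR-192 and miR-451 were chosen after their values were seen.

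For single miRNAs 0 passed between the sexes by limma over all 710, and 78 had an unadjusted p under 0.05 (38 higher, 40 lower in females). miR-211 (adjusted p = 0.121) was at the floor in 5 of 6 males, and its fitted difference of 3.55 was 0.53 with a floor of 16. It passed without knockout replicate 6, the only female at the floor (adjusted p = 0.000307), which sets dim values against the floor. Without knockout replicate 5, miR-380-3p, at the floor in 3 females, passed (0.0179), a name taken after its value was seen. The X chromosome list had a median of 0.01 (adjusted p = 0.956). Its leading members were miR-878-5p, at the floor in 2 females (-2.84 ± 1.07), and miR-188-3p, at 0.44 ± 0.18, and neither passed (adjusted p = 0.404 and 0.438). Of the other lists between the sexes, none passed camera: myeloid (-0.06), muscle (0.42), brain (-0.03), miR-17-92 (-0.15), inflammation (0.10), glucose and lipid metabolism (0.20), the miR-34 family (-0.15) and the Dlk1-Dio3 cluster (0.11), with adjusted p from 0.167 to 0.956. By fry's mixed test, which counts changes in either direction, 9 of the 15 lists passed between the sexes. Among them were glucose and lipid metabolism (adjusted p = 0.000649), myeloid (0.00641), Dlk1-Dio3 (0.0233) and the wider miR-34 family list (0.0401). When adjusted over the list alone, 1 member passed in the glucose and lipid list (miR-122) and 1 in the miR-34 family list. That member was miR-192, which is not a miR-34 miRNA and is also in the liver and gut epithelium list. miR-34a, miR-34b-3p, miR-34b-5p and miR-34c had unadjusted limma p from 0.0740 to 0.176, the first 3 named after their values were seen.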

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

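The tests on the Sfmbt2 locus, on shared probe signal, on the miR-181 family and on miR-122 were chosen only after these results were seen; the splits of the samples and the relation to array brightness were set down before their outcome was known.

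A sample far from the other 5 of its genotype was found in 7 of 120 groups of 6 values, where chance gives about 6. Knockout replicate 1 had the lowest miR-1937a (14.69 on the log2 scale, the other 5 tied at 15.48, the top value that all arrays share, which sets the gap) and the highest miR-16 (15.48, next 14.82). Knockout replicate 3 had the highest miR-30b (13.75, next 13.34). Wild type replicate 1 had the lowest miR-206 (1.84, next 4.73). Wild type replicate 5 was at the floor for miR-539 (0 on the log2 scale, next 3.98) and had the lowest mean of the miR-34 family list (5.70, next 7.09). Wild type replicate 2 had the lowest mean of the Dlk1-Dio3 list (5.27, next 5.55). Between the sexes, the genotype difference of the Sfmbt2 family differed by a median of 0.35 on the log2 scale.

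By camera with the preset correlation the miR-297, miR-466, miR-467 and miR-669 family was higher in knockout blood, a call that is lost with an estimated correlation (adjusted p = 0.408), in fry (0.203) and in the exact permutation of list means (0.487). Array brightness argues little for it: over the 12 raw arrays the family mean had r = -0.155 with log2 median raw intensity (Pearson, permutation p = 0.638; Spearman rho = -0.242, p = 0.446; adjusted p = 0.638 for both; r = -0.116 without the 2 arrays farthest from the median; r = -0.234 within knockout and -0.350 within wild type). A change at the Sfmbt2 locus alone, each probe reading only its own miRNA, would leave members encoded elsewhere in place. The mean of the 7 members with no hairpin there differed by 0.63 (exact permutation p = 0.0346, not adjusted), against 0.40 for the 42 inside. The medians were closer, at 0.37 and 0.35. The outside mean was led by miR-467f (1.66), already seen among the smallest p, and miR-466i (1.30), while miR-466j and miR-669n were at 0.01 and 0.05. These values do not decide against the locus. Probes of similar sequence reading one another's signal would need the outside members to shift and may account for it, although a change of the whole family would look alike. Whether there is a rise to explain stays open, as do genotype and any difference between the mice that goes with it.

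The miR-181 family was lower in knockout blood, with a mean over the 4 members of 6.52 ± 0.46 in knockout and 7.44 ± 0.45 in wild type mice (log2, SD, n = 6 each). These members were singled out by their values, so no test of their mean is given, and miR-181d alone was at -0.34 ± 0.32 (SE). A smaller share of lymphocytes cannot be told apart: the lymphocyte-enriched miR-150, miR-155 and miR-342-3p had a median of 0.14 but split, at 0.14, 0.67 and -0.63 (SD 0.65), and most of the other lymphoid markers are broadly expressed. Whether the probes of miR-181a to miR-181d read one another cannot be told apart from a change of each, since all 4 were lower and no probe sequences were used here. A change within 1 lymphocyte class stays a hypothesis that was not tested.

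miR-122 was higher in female blood, short of the threshold over all miRNAs (adjusted p = 0.121). The authors' normalization does not account for it: among the knockout mice the raw female minus male difference was 3.45 on the log2 scale, 99.3% of the normalized 3.48. Knockout replicate 6 carries much of it: without that mouse the values were 1.74 and 2.00, or 87.0%. Whether RNA of liver origin contributes cannot be told: the mean of miR-194 and miR-148a, liver-enriched but bright in this blood in both sexes, was 10.58 ± 0.30 in females and 10.45 ± 0.28 in males (log2, SD, n = 6 each; exact permutation p = 0.444). The members of that mean split, with miR-194 at 0.38 ± 0.19 and miR-148a at -0.13 ± 0.23 (female minus male, log2 difference ± SE). miR-192, at 0.96, was left out of that mean because its difference had been seen. Sex and the way blood was drawn stay open and untested.

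Other splits of the same mice were compared by the number of miRNAs with an unadjusted p under 0.05. For knockout against wild type, 6 of 100 splits that kept the sexes balanced gave at least the real 67 (highest other 82), so chance was not excluded. For female against male, 4 of 100 balanced splits gave at least the real 78 (highest other 81). That share is under the limit of 0.05 set beforehand. Both counts include the real split, and 4 and 6 of 100 drawn splits are too close to be read differently. Chance was therefore not firmly excluded here either. For the genotype effect between sexes, 33 of 100 gave at least the real 38; the highest other was 130. These splits exchange sex within genotype, so some of them carry the sex difference itself into the interaction, and they say little about chance. Within 1 sex the 10 splits are too few for a share under 0.05: in males 3 gave at least the real 36 (highest other 71), and in females 1, the real one with 62 (highest other 60).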

How the results depend on the processing

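The exact permutation of list means and the removal of wild type replicates 5 and 6 together were chosen after seeing the data. For knockout against wild type, the count of 0 was kept under 14 of 15 alternatives and in all 12 fits with a mouse left out (0 to 0); the brightest 25% of miRNAs gave 5, with the shared spread refitted (SE of miR-181a 0.26 in place of 0.29); the cause was not separated from the smaller number tested. The unadjusted count of 67 ranged from 14 to 86 over alternatives that did not all test the same number of miRNAs. The 1 miRNA in males became 0 with a floor of 16, an offset of 16, the brighter 50%, the brightest 25%, eBayes with trend and robust fitting, males alone and the replicate block; both filters on brightness leave miR-654-3p out, and for the rest the cause was not tested. With a mouse left out that count ran from 0 to 3 (3 without wild type replicate 1: miR-654-3p, miR-302b and miR-758). For females the count of 0 became 5 in the brightest 25%, 6 without wild type replicates 5 and 6, where a lone wild type female is assumed to vary like the other groups, and 0 to 1 with a mouse left out. Between the sexes in genotype effect it became 2 with array weights (miR-654-3p and miR-464), 6 without those 2 mice and stayed 0 with any 1 left out. For female against male it became 1 with an offset of 16, 1 in the brighter 50%, 10 in the brightest 25%, and 0 to 2 with a mouse left out (miR-122, miR-380-3p or miR-211).

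The 1 list called between genotypes became 0 with an estimated correlation, fry and exact permutation, and stayed 1 with any mouse left out. The 3 called between the sexes became 0 under the same 3, and 1 to 5 with a mouse left out (1 without knockout replicate 1, 5 without wild type replicate 2). Over 1730 pairs of a list and an alternative, 34 lost and 9 gained a call; medians of lists called in neither changed sign in 150. Without wild type replicates 5 and 6 the interaction of the Sfmbt2 family fell to a median of 0.00369 (camera adjusted p = 0.811), and the direction camera gives it turned. In 1238 of 1242 pairs of a named miRNA and an alternative the direction was kept. Many of these miRNAs were named for a small p in the same values, and the alternatives share most of the arrays. Some alternatives, such as the filters on brightness, leave the fitted difference as it is. The pairs are therefore not independent, and a kept direction was likely in advance. The 4 exceptions were miR-486, at 0.0203 with median scaling of the raw table, 0.0460 without normalization and 0.0305 without wild type replicate 1 (-0.0723 to 0.0305 with a mouse left out), and miR-1937a, at 0.0669 without knockout replicate 1 (-0.109 to 0.0669); their cause was not tested. Over 5 scalings of the raw table the median of all miRNAs moved by at most 0.04, the Sfmbt2 family median was 0.24 to 0.37 and all 4 miR-181 miRNAs stayed lower.

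Replicate numbers did not pair the mice: residuals of same-numbered mice correlated at -0.134 to 0.131, and 1 of 6 knockout mice correlated best with its own number. With the replicate block 0 miRNAs passed between genotypes, 0 in males, 0 in females and 0 for the difference between sexes. Other scalings, normexp and the raw source were not run for the comparisons that need sex, nor was brightness by sex. The names of the wild type raw columns give no sex, and their match to the normalized arrays was not used for it. Without single arrays the knockout minus wild type difference in median raw intensity ran from -10.7 to 12.7. Signal over background limits dim miRNAs, which lack detection calls.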

Other observations

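Several miRNAs named here were chosen after their values were seen, and no explanation was tested for them. In the brightest 25% of miRNAs, 10 passed between the sexes by limma. Higher in females were miR-122, miR-152 (8.44 ± 0.19 in females, 7.81 ± 0.09 in males; log2, SD, n = 6 each), miR-342-3p, miR-709, miR-192 and miR-483. Lower in females were miR-451, let-7i, let-7g and miR-340-5p (largest adjusted p of the 10, limma, 0.0491). The difference was 0.63 for miR-152, 0.93 for miR-709, 0.77 for miR-483 and -0.70 for miR-340-5p on the log2 scale.

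Genotype and sex differences of let-7f went opposite ways, 0.93 for knockout minus wild type and -0.91 for female minus male, and those of miR-122 did too, at -2.19 and 4.03. The 3 knockout females spread from 7.29 to 12.11 in miR-122 on the log2 scale. In females tested within the brightest 25%, 4 of the 5 miRNAs that passed belonged to the miR-466 and miR-467 families (miR-466f-3p, miR-467f, miR-467a* and miR-467d*), all higher in knockout, and the remaining one, miR-2132, was lower (-1.30; adjusted p = 0.0464 for all 5, limma).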
